A study of Mus musculus with 8 samples.

How the data were processed

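Total RNA from mouse aortic vascular smooth muscle cells was measured on 8 single-colour Affymetrix arrays. All cultures had been exposed to adenovirus for 24 h and then to cholesterol at 10 µg/ml for 72 h. The titles name the virus as AdPl on 4 arrays and AdN5 on 4, and the genotype field calls these groups control and NFAT5 overexpression. Each array was placed in its group by its title, and the replicate numbers 1 to 4 were taken from the titles. The labels do not say whether replicates came from separate cultures. The p-values of single genes and of permutation tests therefore measure only the spread between these samples, which may be technical. No batch or scan date was given in the sources used here.

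The deposited values are on the log2 scale and were made with RMA, per the submitters' processing notes, which name no version. RMA corrects the background of each probe, quantile normalises the arrays and summarises the probes of a probe set. The sorted values were identical on 7 arrays, and those of NFAT5 replicate 1 differed from them by at most 0.00183. Quantile normalisation gives each array the same distribution, so a shift of all genes in the same direction could not be seen in these values. RMA also compresses differences of dim genes toward 0. The build and annotation behind the probe sets are not given in the sources used here, and no genome coordinates are reported.

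The table held 25428 probe sets, each keyed by an Entrez gene identifier. The supplied probe table gave 1 gene symbol for 24705 of them and several symbols for 0, and 723 were not listed in it and stay unnamed. For the symbol shared by more than 1 probe set, the brightest was taken, which left 24704 genes. Of the Entrez identifiers, 24673 matched a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only, and 0 symbols changed. No filter on dim genes was applied.

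The groups were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, two-sided), on all 8 arrays and without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 fold changes are standard errors from this fit, and errors of group means are SDs over 4 arrays. The Nfat5 level was also compared by an exact two-sided permutation test over the 70 assignments of the arrays, whose smallest possible p is 0.0286. The scripts were tested on simulated data with known changes, and Python 3.11.15 with matplotlib 3.10.9 drew the figures.

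Lists of genes were fixed before the data were examined. The 25 gene lists were NFAT5 targets and osmotic stress genes, cholesterol biosynthesis, cholesterol uptake, efflux and LXR targets, fatty acid synthesis, fatty acid oxidation and lipid droplets, smooth muscle contractile genes, synthetic and modulated smooth muscle markers, extracellular matrix and remodelling, osteochondrogenic genes, TGF-beta response, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, antigen presentation, cell cycle and DNA replication, p53 targets and growth arrest, the unfolded protein response and ATF4 targets, oxidative stress and NRF2 targets, heat shock proteins, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, ribosomal proteins, ion channels and amino acid or organic osmolyte transporters, Wnt signalling, and Notch signalling. The 8 cell type marker lists covered endothelial cells, macrophages, fibroblasts or adventitial cells, adipocytes, T or B lymphocytes, chondrocytes, mesothelial or epithelial cells, and nerve or Schwann cells. Of the 570 gene list entries 522 were measured, and of the 90 marker entries 82; the remaining entries were not analysed here. Each list was tested against all other genes with camera from limma at the preset inter-gene correlation of 0.01, with adjustment within each family of lists. Its p-values set members against other genes under that assumed correlation, so they do not measure the spread of list means between arrays. A list mean is the average log2 fold change of its measured members.

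The genes named in the text were set by a rule. They are Nfat5, the 12 genes with the largest and the 12 with the smallest log2 fold change among called genes whose groups did not overlap (leaving out predicted genes, microRNAs, small nucleolar RNAs, RIKEN clones and pseudogenes), and the 2 measured members at either end of each list. Called members named beyond those ends, and all genes named in the other observations, were chosen after their values were seen.

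The alternatives were the replicate number as a block, renewed quantile normalisation, median centring, filters at the lower quartile or at the median of expression, the mean over probe sets, every probe set by itself, a variance trend with robust estimation, array weights, each array left out in turn, a fold change of at least 1.5, an adjusted p under 0.01, camera with an estimated correlation, fry, and camera on ranks. A fit without control replicate 3 and NFAT5 replicate 4 was added after seeing the data. No column of values was left out.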

Results

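Expression was measured in mouse aortic vascular smooth muscle cells, the contractile cells of the arterial wall, after infection with an adenovirus and loading with cholesterol at 10 µg/ml for 72 h. The 4 control arrays carried the virus titled AdPl, and the 4 arrays labelled NFAT5 carried the virus titled AdN5, described as NFAT5 overexpression. NFAT5 is a transcription factor of the response to osmotic stress, and the comparison asks how its overexpression alters the transcriptome of cholesterol-exposed smooth muscle cells. The values were the deposited log2 RMA values of 24704 genes. Pairs of arrays correlated at 0.992 to 0.993 within the control group, at 0.990 to 0.992 within the group labelled NFAT5 and at 0.989 to 0.992 between the groups, across genes. PC1 held 22.0% of the variance and separated the groups. PC2 held 17.1%, with control replicate 3 (14.2) and NFAT5 replicate 4 (24.7) at its positive end, NFAT5 replicates 2 (-11.1) and 3 (-19.5) at its negative end and the other arrays between -3.25 and 0.337. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.11.

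Nfat5 itself was not higher in the arrays labelled NFAT5. Its single probe set had a mean log2 level of 6.97 ± 0.072 (SD, n = 4) in these arrays and of 7.16 ± 0.089 (SD, n = 4) in the control arrays. The log2 fold change was -0.19 ± 0.078 (SE), with a 95% interval from -0.36 to -0.013, an adjusted p of 0.360 in limma and an exact two-sided permutation p of 0.0571. The level lay at the 84.3 percentile of all genes, well within the measured range. The measured transcript thus goes against the label, and the groups are called NFAT5-labelled and control below, with every direction drawn from the labels. Positions of the probes are not given in the sources used here, and a virus can carry a coding sequence without untranslated regions, so this probe set may not read the transgene.

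In the NFAT5-labelled arrays 192 genes passed an adjusted p of 0.05, 90 of them higher and 102 lower than in the control arrays. The leading higher genes were E2f8, an atypical E2F repressor active in cycling cells (log2 fold change 1.31 ± 0.16), Sprr2e, a small proline-rich protein (1.15 ± 0.17), Nos2, the inducible nitric oxide synthase (1.09 ± 0.092), Ms4a14 (1.00 ± 0.12) and Grem1, a secreted antagonist of bone morphogenetic proteins (0.99 ± 0.069). They were followed by Ccne2, encoding cyclin E2 (0.93), the dicarboxylate transporter Slc13a3 (0.93), the 5S ribosomal RNA gene n-R5s136 (0.89), the scavenger receptor Cd36 (0.85), the ubiquitin ligase receptor Dtl (0.85), Ccna2, encoding cyclin A2 (0.84), and the chemokine Ccl5 (0.83). The lower genes reached larger changes. Chl1, a neural cell adhesion molecule, fell by 2.07 ± 0.094 to 0.239 of the control level (adjusted p = 4.39e-05 in limma). Hpgd, the prostaglandin-degrading dehydrogenase, fell by 1.91 ± 0.13, the secreted Wnt modulator Sfrp2 by 1.62 ± 0.12 and the sodium channel gene Scn7a by 1.44 ± 0.12. Elobl (-1.30), Sprr1a (-1.26), Ly6c1 (-1.24), the melanocyte antigen gene Mlana (-1.24), the fatty acid binding protein gene Fabp7 (-1.22), the complement component C7 (-1.07), the synuclein gene Sncg (-1.06) and the peptide gene Ostn (-1.05) completed this end. Some leading genes were dim, below the median probe set of an array (3.76). In the control arrays these were Sprr2e (2.84), Ms4a14 (3.01) and C7 (3.62). In the NFAT5-labelled arrays they were C7 (2.54), Ly6c1 (2.79), Ostn (3.37), Hpgd (3.49) and Scn7a (3.54). RMA compresses differences of dim genes, so the sizes of these changes are uncertain.

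**Figure D1:**
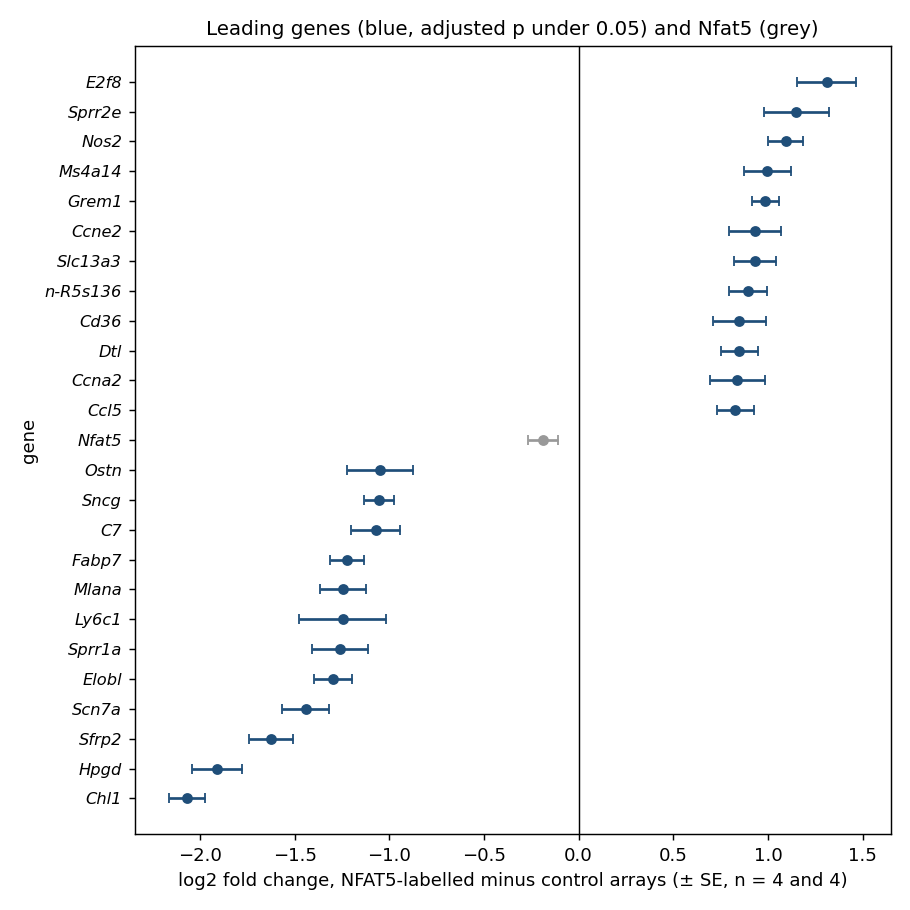
Log2 fold change (x axis, NFAT5-labelled minus control arrays, n = 4 and 4) of the leading called genes and of Nfat5 (y axis), with points for the estimates and bars for the standard errors. The called genes run from -2.07 for Chl1 to 1.31 for E2f8, and Nfat5 lies at -0.19 without passing the threshold.

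All 192 genes had groups that did not overlap, as did 8.78% of all genes, against 2.86% by chance for 4 against 4. The change was at least 1.5-fold for 110 genes and at least 2-fold for 22, of which 4 were higher and 18 lower. At an unadjusted p under 0.05 there were 3097 genes. The count moved with the setting, to 42 at an adjusted p under 0.01, 497 among genes above the median, 781 with a variance trend and robust estimation and 30 without control replicate 3 and NFAT5 replicate 4, the last chosen after seeing the data. It was 56, 57, 86 and 59 without control replicates 1 to 4 and 85, 86, 78 and 88 without NFAT5 replicates 1 to 4. All 192 genes kept their sign, as genes whose groups do not overlap must when an array is left out. Among the leading genes Cd36 was called in 0 of those 8 fits (adjusted p up to 0.102), Ly6c1 in 1 (up to 0.145), Sprr2e in 2 (0.0829), Ccna2 in 2 (0.123), Ostn in 2 (0.104) and Ccne2 in 3 (0.0713), and the others in all 8.

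Genes of the cell cycle and DNA replication rose as a list in the NFAT5-labelled arrays. The mean of its 31 measured genes was 5.68 ± 0.15 (SD, n = 4) in the NFAT5-labelled arrays and 5.29 ± 0.064 in the control arrays, a mean log2 fold change of 0.39 (camera adjusted p = 1.90e-16; adjusted p = 0.250 with an estimated correlation). Of these genes 7 rose, 0 fell and 24 did not pass, and 19 rose when adjusted over the list alone. The cyclin genes Ccne2 (0.93) and Ccna2 (0.84) led, and Mcm6, a subunit of the replicative helicase, rose by 0.60 ± 0.080. At the other end the values were -0.052 for thymidine kinase Tk1 and -0.11 for Ccnd1, encoding cyclin D1, neither past the threshold. In the same arrays the mean of the macrophage markers was higher by 0.33.

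Inflammatory cytokines and NF-kB targets also rose, by a mean of 0.22 over 28 genes (camera adjusted p = 8.31e-06; adjusted p = 0.250 with an estimated correlation). Nos2, Ccl5, Ptgs2 (0.69), the cyclooxygenase of inflammation, Tnf (0.58) and Ccl7 (0.51) rose, 0 genes fell and 23 did not pass. Adjusted over the list alone, 14 were higher and 3 lower. Cxcl2 was at 0.86, Csf2 at -0.38 and the alarmin gene Il33 at -0.41, without passing. Cxcl2 (2.58 in the control arrays) and Csf2 (2.48) were dim genes. The call of Tnf was kept in 1 of 8 fits with an array left out (adjusted p up to 0.0952). The 28 interferon-stimulated genes rose by a mean of 0.15 (camera adjusted p = 4.88e-05; adjusted p = 0.497 with an estimated correlation), although 0 single genes passed and 6 were higher when adjusted over the list alone. Of them 23 were higher and 5 lower, and the list means of the arrays overlapped between the groups (exact permutation p = 0.0857). Its ends were the antiviral genes Oas1a (0.59) and Oas3 (0.56) and, lower, Ifnb1 (-0.13) and Ifit3 (-0.14). Ifnb1 was dim (2.17 in the control arrays), so its value says little. Antigen presentation genes rose by a mean of 0.10 over 16 genes (camera adjusted p = 0.0164; adjusted p = 0.295 with an estimated correlation), with 0 single genes past the threshold and 2 higher when adjusted over the list alone. Here too the list means of the arrays overlapped between the groups (exact permutation p = 0.0857). H2-Ab1 was at 0.35, Psmb8 at 0.27, Nlrc5 at -0.14 and Ciita at -0.15. The antigen presentation call was lost without control replicate 1 (adjusted p = 0.0532), control replicate 2 (0.0579) or NFAT5 replicate 2 (0.0916). The macrophage marker mean was higher by 0.33 in these arrays as well.

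Among markers of other cell types those of macrophages rose and those of fibroblasts fell. The 13 macrophage markers had a mean of 5.76 ± 0.092 (SD, n = 4) in the NFAT5-labelled arrays against 5.43 ± 0.066 in the control arrays, and all 13 fold changes were above 0 (mean 0.33, camera adjusted p = 5.89e-09; adjusted p = 0.0416 with an estimated correlation). Adgre1, encoding the macrophage antigen F4/80, rose by 0.68 ± 0.083, Laptm5 by 0.53 ± 0.086 and Cd68 by 0.52 ± 0.088, 10 genes did not pass, and 7 rose when adjusted over the list alone. Csf1r (0.14) and Cd14 (0.11) were the smallest changes. Laptm5 was called in 1 of 8 fits with an array left out (adjusted p up to 0.0916). The 13 fibroblast or adventitial markers fell by a mean of 0.28 on the log2 scale, from 6.95 ± 0.016 to 6.68 ± 0.063 (camera adjusted p = 1.48e-05; adjusted p = 0.0217 with an estimated correlation). Ly6c1 fell, 12 genes did not pass, and 6 fell when adjusted over the list alone. Cd34 was at -0.53, Clec3b at 0.061 and Tcf21 at 0.0065.

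The remaining marker lists did not pass, and 0 of their genes were called. Control means were 2.78 for lymphocyte, 3.41 for adipocyte, 3.41 for nerve, 3.62 for mesothelial and 3.64 for chondrocyte markers. These lie below the median probe set of a control array (3.76), so the absence of a shift says little for them. The endothelial control mean was 4.27. The means were -0.030 for 14 endothelial markers (adjusted p = 0.662), -0.067 for 7 adipocyte markers (0.458; 0.0433 for the 2 above the median gene; median 0.0049), 0.096 for 10 T or B lymphocyte markers (0.241), -0.045 for 9 chondrocyte markers (0.597), -0.044 for 9 mesothelial or epithelial markers (0.660) and 0.019 for 7 nerve or Schwann cell markers (0.764). Adjusted over the list alone, 1 adipocyte and 1 chondrocyte marker were lower and 0 genes of the other lists passed. Among the ends of these lists were the endothelial Cdh5 (0.35) and Egfl7 (-0.31), the adipocyte regulator Pparg (-0.36), the T cell gene Cd4 (0.39), the cartilage collagen gene Col11a1 (-0.42), the keratin gene Krt19 (-0.27) and S100b (-0.27).

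**Figure D2:**
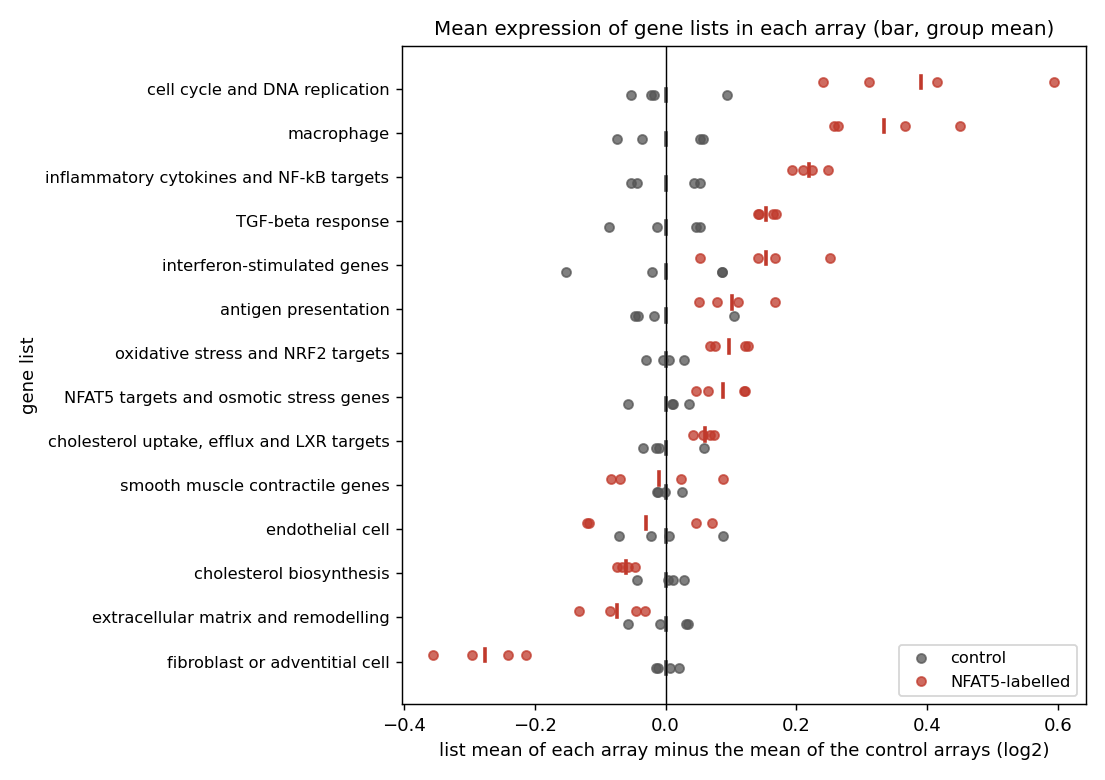
Mean log2 expression of 14 gene lists in each array minus the mean of the control arrays (x axis, log2), with dots for arrays, bars for group means, grey for control and red for NFAT5-labelled arrays. The groups separate for the cell cycle list, at 0.39, and for the macrophage markers, at 0.33, and lie in the opposite order for the fibroblast markers, at -0.28.

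Lists of cholesterol and lipid metabolism did not pass camera. The 20 cholesterol biosynthesis genes had a mean of -0.061 (adjusted p = 0.168; 0.0209 with fry, which does not set a list against other genes). Hsd17b7, a late enzyme of the pathway, rose by 0.59 ± 0.11 and Insig1, which holds the sterol sensor in the endoplasmic reticulum, fell by 0.49 ± 0.076. The others did not pass, among them Mvk (0.26) and Cyp51 (-0.34), and adjusted over the list alone 1 gene was higher and 3 lower. The mean of the 21 genes of cholesterol uptake, efflux and LXR targets was 0.060 (adjusted p = 0.568), with the median at -0.0018. Its risen members were Cd36 and Olr1 (0.64 ± 0.083), both scavenger receptors that bind oxidised low-density lipoprotein, while Smpdl3a (-0.45) and Nr1h3 (-0.41), encoding LXR-alpha, did not pass. Adjusted over the list alone, 4 were higher and 2 lower. The call of Insig1 was kept in 1, that of Hsd17b7 in 0 and that of Olr1 in 8 of 8 fits with an array left out. The macrophage marker mean was higher by 0.33 in the arrays in which the scavenger receptors rose. The 23 fatty acid synthesis genes had a mean of -0.088 (adjusted p = 0.0784; 0.0254 with a variance trend and robust estimation, 0.0330 with fry, 0.0465 without control replicate 3 and 0.0436 without control replicate 3 and NFAT5 replicate 4), 0 passed over all genes and 2 were lower over the list alone. Acss2 was at -0.61, Scd1 at -0.52, Elovl6 at 0.37 and Acly at 0.16. Fatty acid oxidation and lipid droplet genes had a mean of -0.0029 and a median of 0.031 over 23 genes (adjusted p = 0.812, camera direction up). The monoglyceride lipase gene Mgll fell by 0.51 ± 0.083 (called in 0 of 8 fits with an array left out), Lpl was at -0.58, Angptl4 at 0.30 and Pdk4 at 0.30, and 5 genes passed when adjusted over the list alone.

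Smooth muscle contractile genes showed no shift that passed the test. Their mean over 21 genes was -0.010 and their median 0.013 (camera adjusted p = 0.714). Over all genes 0 passed, and 2 were lower when adjusted over the list alone. Acta2, the smooth muscle actin gene, was at -0.30 ± 0.071, with a level of 11.74 ± 0.079 against 12.04 ± 0.021 (SD, n = 4). Aoc3 was at -0.38, Kcnmb1 at 0.34 and the calponin gene Cnn1 at 0.33. The 18 synthetic and modulated markers had a mean of -0.042 (adjusted p = 0.714). S100a4, a calcium-binding protein, fell by 0.65 ± 0.11 (called in 0 of 8 fits with an array left out), and Mgp (0.31), Timp1 (0.26) and Lum (-0.45) did not pass; adjusted over the list alone 1 was higher and 2 lower.

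Extracellular matrix genes fell by a mean of 0.074 on the log2 scale over 27 genes (camera adjusted p = 0.0348; adjusted p = 0.572 with an estimated correlation). The list means of the arrays overlapped between the groups (exact permutation p = 0.0857). The metalloprotease gene Adamts1 (-0.65 ± 0.071) and the matricellular gene Postn (-0.41 ± 0.075) fell, 25 did not pass, and adjusted over the list alone 1 was higher and 3 lower. Mmp2 (0.31) and Mmp9 (0.31), both encoding gelatinases, lay at the upper end. The list lost its call without control replicate 1 (adjusted p = 0.115), control replicate 2 (0.0536), control replicate 4 (0.0986), NFAT5 replicate 2 (0.0916) or NFAT5 replicate 4 (0.170), and Postn in all 8 such fits. TGF-beta response genes rose by a mean of 0.15 over 17 genes (camera adjusted p = 0.00119; adjusted p = 0.295 with an estimated correlation). Ltbp2, a latent TGF-beta binding protein, rose by 0.71 ± 0.084, Ankrd1 by 0.47 ± 0.068 and Tgfb3 by 0.42 ± 0.068, Id3 fell by 0.44 ± 0.081, and Tgfbi was at -0.26 without passing. Adjusted over the list alone, 7 were higher and 2 lower. Ankrd1 was called in 1 and Id3 in 0 of 8 fits with an array left out. The mean of the fibroblast markers was -0.28 in the same arrays. The 14 osteochondrogenic genes had a mean of -0.12 (adjusted p = 0.117), with 0 genes past the threshold and 2 lower over the list alone, and Bglap was at -0.56, Alpl at -0.39, Ank at 0.22 and Col10a1 at 0.15. For 13 Wnt signalling genes the mean was -0.16 and the median -0.072 (camera adjusted p = 0.117; 0.0243 with a variance trend and robust estimation, 0.0129 with fry and 0.375 on ranks). Sfrp2 was the only called member and also the only gene past the threshold over the list alone. Nkd2 was at -0.24, Wnt5a at 0.18 and Fzd1 at 0.14. Notch signalling genes had a mean of 0.034 over 10 genes (adjusted p = 0.608), 0 genes passed on either count, and Notch2 was at 0.33 and Heyl at -0.32.

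**Figure D3:**
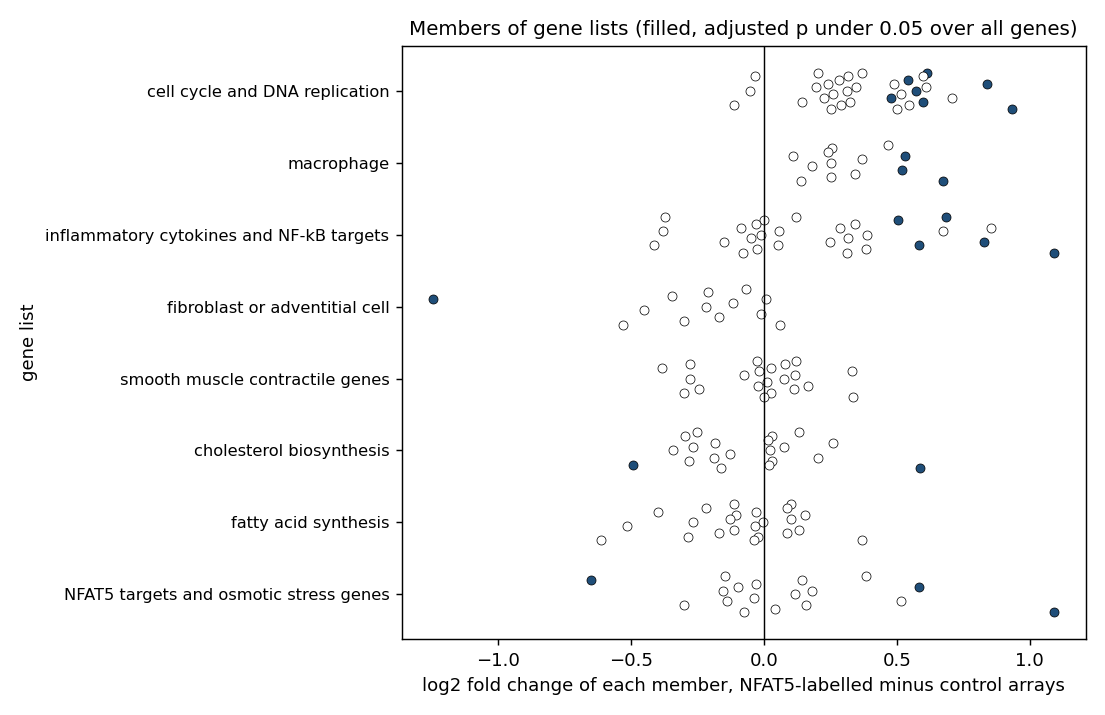
Log2 fold change (x axis, NFAT5-labelled minus control arrays) of each member of 8 lists (y axis), with filled points for an adjusted p under 0.05 over all genes. Cell cycle members reach 0.93 and macrophage markers 0.68, while the contractile genes lie between -0.38 and 0.34 with 0 of them filled.

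NFAT5 targets and osmotic stress genes did not pass camera, with a mean of 0.088 and a median of 0.0061 over 18 genes (adjusted p = 0.446; 0.0330 with fry). Nos2 (1.09) and Tnf (0.58), which the inflammatory list also holds, rose, S100a4 fell by 0.65, and 15 did not pass; adjusted over the list alone 4 were higher and 2 lower. Slc38a2, an amino acid transporter of the osmotic response, was at -0.30. The list means of the groups did not overlap, at 6.61 ± 0.038 against 6.53 ± 0.040 (exact permutation p = 0.0286, the smallest possible; SD, n = 4). This was not particular to NFAT5 targets, as 9 of the 25 gene lists separated. Among them were cholesterol biosynthesis, fatty acid synthesis, synthetic markers and Wnt signalling, which did not pass camera either. Over the 14 members outside the inflammatory list the mean log2 fold change was -0.031 (exact permutation p = 0.429).

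Oxidative stress and NRF2 targets rose by a mean of 0.098 over 25 genes (camera adjusted p = 0.0348; adjusted p = 0.295 with an estimated correlation). The risen members were Cybb, encoding the phagocyte NADPH oxidase subunit (0.58 ± 0.088), and the metallothionein gene Mt1 (0.44 ± 0.075), with 23 not past the threshold, Gpx3 at -0.18 and Gstm1 at -0.21, and 4 were higher over the list alone. Leaving out control replicate 1 (adjusted p = 0.0930), control replicate 4 (0.0573), NFAT5 replicate 2 (0.0916) or NFAT5 replicate 3 (0.0509) ended the call of the list, and Cybb was called in 1 and Mt1 in 0 of the 8 such fits. The macrophage marker mean was higher by 0.33 in these arrays. Lysosome and autophagy genes had a mean of -0.0099 and a median of 0.00050 over 22 genes (adjusted p = 0.610). Ctss, encoding a cathepsin abundant in phagocytes, rose by 0.61 ± 0.10 (called in 1 of 8 fits with an array left out), Hexa was at 0.27, Ctsk at -0.30 and Tfeb at -0.37, and adjusted over the list alone 2 were higher and 2 lower.

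The other stress and metabolic lists did not pass. The unfolded protein response and ATF4 targets had a mean of -0.038 over 23 genes (adjusted p = 0.567), with 0 genes past the threshold over all genes but 3 higher and 5 lower over the list alone, and with Aldh1l2 (-0.51), Trib3 (-0.42) and Ddit3 (0.36) at its ends. For p53 targets and growth arrest the mean was -0.050 over 22 genes (adjusted p = 0.349), and Cdkn2a was at -0.35 and Pmaip1 at 0.23. Heat shock proteins averaged 0.064 over 14 genes (adjusted p = 0.295), with Hsp90aa1 at 0.30 and Cryab at -0.12, and glycolysis and hypoxia genes averaged 0.044 over 21 genes (0.568), with Pgam1 at 0.46 and Egln3 at -0.29. The mean was -0.060 for 28 genes of oxidative phosphorylation (adjusted p = 0.167), with Ndufa4 at -0.28 and Atp5h, a dim gene (3.07 in the control arrays), at -0.82. For 19 ribosomal protein genes it was 0.032 (adjusted p = 0.541), with Rpl7 at 0.56 and Rps14 at -0.45. Rps14 varied widely, with an SD of 0.72 over the NFAT5-labelled arrays. The control mean of the ribosomal list was 5.34. Its members Rpl19 (3.47) and Rpl37 (2.87) lay below the median probe set of a control array (3.76), so an absent shift says little for them. In these 5 lists 0 genes passed on either count. Ion channels and amino acid or organic osmolyte transporters had a mean of -0.079 over 20 genes (adjusted p = 0.134; 0.0448 above the lower quartile of expression, 0.0305 with a variance trend and robust estimation and 0.0474 without NFAT5 replicate 3). The glycine transporter gene Slc6a9 fell by 0.87 ± 0.12 (called in 5 of 8 fits with an array left out), Slc7a5 was at -0.49, Slc38a4 at 0.20 and Trpc6 at 0.19, and 3 were lower over the list alone.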

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

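Tests on the Nfat5 probe set, on a lower share of smooth muscle cells, on dim macrophage probe sets and on S phase lists without genes already seen were chosen only after the result was seen. Of the 35 splits of the 8 arrays into equal groups, 1, the real split, gave as many as 192 called genes. The highest count among the others was 0. This argues against chance for that count only at 1 in 35, the smallest share these splits allow. The other splits mix the groups, so a technical difference between the groups would give the same outcome.

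The Nfat5 probe set was not higher in the arrays labelled NFAT5. The upper bound of the 95% interval of the log2 fold change was -0.013, which argues against a 2-fold rise of the summarised probe set signal. Single probes were not examined, so a transcript read by only some of them cannot be judged. Exchanged labels cannot be told apart from correct ones by the NFAT5 target members outside the inflammatory list, whose mean over 14 genes was -0.031 (95% interval -0.12 to 0.060, exact permutation p = 0.429). A transgene that lacks the sequence read by the probe set stays open, because probe positions are not given, and an effect of the virus on the native transcript may add to it. The biological difference named by the design was not tested apart from these, and the measured values do not show that NFAT5 was overexpressed.

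Macrophage markers were higher in the NFAT5-labelled arrays by a mean of 0.33 over 13 genes that no other fixed list holds, led by Adgre1 at 8.39 against 7.72, Laptm5 at 8.21 against 7.68 and Cd68 at 8.65 against 8.12. A lower share of smooth muscle cells would raise the markers of every other type alike. Fibroblast markers moved the opposite way, 0.61 below the macrophage markers (95% interval 0.40 to 0.82, exact permutation p = 0.0286). Both means were known before, and the fibroblast list shares Lum and Dcn with the modulated smooth muscle list, so this comparison does not decide it. The contractile list had no shift that passed (mean -0.010, camera adjusted p = 0.714). The rise did not rest on dim probe sets, since the 11 of these markers above the median gene had a mean of 0.35 (95% interval 0.20 to 0.50). They are members of the same list, so this is no separate test. A larger share of macrophages is consistent with another list of 25 macrophage genes, at 0.35 (95% interval 0.24 to 0.45, exact permutation p = 0.0286) with 22 values above 0, but within it Cd53 (-0.054 at a mean level of 7.20 over all arrays), Coro1a (-0.020) and Vav1 (-0.018) did not follow. Smooth muscle cells that raise macrophage genes under the virus labelled NFAT5 stay open as untested, and the labels name no sort that would remove macrophages.

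The change of S phase genes was larger than that of mitotic genes, on lists written after the cell cycle list and the leading genes were seen. The mean change was 0.34 over 41 S phase genes and 0.20 over 52 genes of the G2 and M phases, a difference of 0.14 (95% interval 0.089 to 0.19, exact permutation p = 0.0286), and 0.14 among members above the median gene. Without the leading genes E2f8, Ccne2 and Dtl, which had prompted the pattern, the difference was 0.084 (95% interval 0.028 to 0.14, exact permutation p = 0.0571) and 0.063 above the median gene (permutation p = 0.0571), and without the fixed cell cycle list as well it was 0.13 (permutation p = 0.0286) and 0.085 (permutation p = 0.0286). The difference above the median gene over all members (95% interval 0.099 to 0.18) does not decide whether compression of dim mitotic genes made the pattern. It includes the leading genes, and without them its permutation p was 0.0571. The mitotic list did not have the dimmer signal (control mean 4.80 against 4.53). A rise of S phase genes beyond mitotic genes stays open, because its test depends on which seen genes are left out, and which cells of the culture were cycling was not tested.

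An array far from the other 3 of its group was found in 19 of 364 groups of values, or 5.22%, about the 1 in 20 that chance gives. The outlying log2 values were 2.80 for Ms4a14 in control replicate 2, 12.23 for Timp1 in NFAT5 replicate 3, 1.72 for Csf2 in NFAT5 replicate 4, 4.76 for Nlrc5 in NFAT5 replicate 4 and 3.86 for Ciita in NFAT5 replicate 1. For Ccnd1 it was 8.89 in NFAT5 replicate 4, for Dnaja1 4.88 in control replicate 4, for Hexa 10.30 in control replicate 1, for Rpl37 2.53 in NFAT5 replicate 1 and for Wnt5a 5.08 in control replicate 3. Further values were 5.01 for Hey2 in NFAT5 replicate 3, 2.67 for Adipoq in NFAT5 replicate 1, 3.30 for Pax5 in NFAT5 replicate 2, 5.67 for Col11a1 in control replicate 3, 5.10 for Upk1b in NFAT5 replicate 3, 2.81 for Krt18 in control replicate 3 and 5.37 for Tubb3 in NFAT5 replicate 3. The ribosomal protein list mean was 5.24 in NFAT5 replicate 2, and the mean of the ion channel and transporter list was 5.90 in control replicate 4.

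Among the 723 probe sets without a gene name, which entered no comparison above, 5 passed an adjusted p of 0.05 in limma, 3 higher and 2 lower, with log2 fold changes between -0.72 and 0.82. That is 0.692% of them, against 0.777% of the named probe sets.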

How the results depend on the processing

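The fit without control replicate 3 and NFAT5 replicate 4 was chosen after seeing the data; the others were planned. Renewed quantile normalisation, median centring and the probe-set mean left the count of called genes within 1.5 times of 192, as did array weights (194), every probe set by itself (197) and genes above the lower quartile (274). The count was 497 among genes above the median, where fewer genes were tested, and 781 with the variance trend and robust estimation, which kept 190 of the 192. It was 110 at a fold change of at least 1.5, 42 at an adjusted p under 0.01, 30 without control replicate 3 and NFAT5 replicate 4, and 56 to 88 with an array left out. All of the 192 tested with an array left out, a filter, the block or another variance model kept their sign. That was fixed in advance, because their groups did not overlap and none of these settings can then turn the sign. With the replicate number as a block the count was 14, all among the 192. Deviations of same-numbered arrays, however, correlated at only 0.055, 0.051, -0.079 and -0.047, and not every array correlated best with its own number. The numbers are therefore not taken to pair the arrays. In simulated data of 24704 genes, 31.3% of genes changed by 0.5 on the log2 scale were recovered, 79.1% at 1 and 100% at 2, so 4 arrays per group leave most changes near 0.5 undetected.

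Of the 25 gene lists 7 passed, against 0 with an estimated correlation, 4 with camera on ranks and 4 to 8 with an array left out; the 2 marker calls held in each of these. With an estimated correlation the adjusted p was 0.572 for extracellular matrix, 0.295 for TGF-beta, 0.497 for interferon-stimulated, 0.250 for inflammatory, 0.295 for antigen presentation, 0.250 for cell cycle and 0.295 for NRF2 genes. Extracellular matrix was at 0.0865 and NRF2 at 0.0611 under the replicate block, both at 0.0692 among genes above the median, and both at 0.128 on ranks. On ranks antigen presentation was at 0.0516. With fry, which does not set a list against other genes, NFAT5 targets (0.0330), cholesterol biosynthesis (0.0209), fatty acid synthesis (0.0330) and Wnt signalling (0.0129) passed, and extracellular matrix (0.0839), interferon-stimulated (0.105) and antigen presentation (0.0568) did not. With an array left out, NFAT5 targets ran from 0.299 to 0.611 and cholesterol biosynthesis from 0.179 to 0.258. Lists also passed newly with the variance trend and robust estimation (fatty acid synthesis 0.0254, ion channels 0.0305, Wnt 0.0243), above the lower quartile (ion channels 0.0448), above the median (adipocyte markers 0.0433), without control replicate 3 (fatty acid synthesis 0.0465), without NFAT5 replicate 3 (ion channels 0.0474) and without control replicate 3 and NFAT5 replicate 4 (fatty acid synthesis 0.0436). With an array left out the adjusted p ran from 0.00977 to 0.170 for extracellular matrix, 0.00362 to 0.0916 for antigen presentation and 0.0190 to 0.0930 for NRF2 genes. The run with an estimated correlation changed only how camera treats that correlation, so the 7 gene list calls depend on the preset of 0.01. For calls lost other than by this or by fewer arrays or genes, the cause was not tested.

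Values of named genes kept direction and side of the threshold in 1340 cases, no longer passed in 55, newly passed in 49 and turned in 6; with an array left out these were 1046, 131, 1 and 14. Reversals were confined to results that were not called. The contractile list turned among genes above the median (adjusted p = 0.900) and on ranks (0.945), lysosome with the variance trend and robust estimation (0.971), and fatty acid oxidation without control replicate 3 and NFAT5 replicate 4 (0.808). That last fit also turned Ifit3 (0.061), Nlrc5 (0.013), Ciita (0.014), Gstm1 (0.087), Cd79b (0.059) and Th (0.014). With an array left out, log2 fold changes ran from -0.066 to 0.12 for Tcf21, -0.020 to 0.27 for Lep, -0.017 to 0.18 for Cd14, -0.12 to 0.0057 for Tk1, -0.22 to 0.061 for Th, -0.29 to 0.047 for Ifit3, -0.20 to 0.016 for Nlrc5, -0.32 to 0.014 for Gstm1 and -0.13 to 0.010 for Cd79b. Adjusted p ran from 0.447 to 0.994 for fatty acid oxidation, 0.472 to 0.884 for nerve, 0.356 to 0.970 for endothelial, 0.378 to 0.849 for Notch and 0.351 to 0.960 for contractile genes.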

Other observations

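The called genes here were chosen after their values were seen, and no group of them was tested. In the NFAT5-labelled arrays Lrg1 fell by 1.01 ± 0.14 on the log2 scale, Saa1, an acute-phase gene, by 0.90 ± 0.16, the haptoglobin gene Hp by 0.59 ± 0.075, the lipopolysaccharide binding protein gene Lbp by 0.54 ± 0.099 and the serpin gene Serpina3n by 0.46 ± 0.075. Rspo2 was at -0.84 ± 0.079, Rspo3 at -0.50 ± 0.071, Igfbp3 at -0.78 ± 0.097 and Ccn3 at -0.61 ± 0.072. Rcan1, a calcineurin regulator, rose by 0.76 ± 0.073, and its relative Rcan2 fell by 0.56 ± 0.10. C3ar1, the receptor for a complement fragment, rose by 0.73 ± 0.11, Selplg by 0.73 ± 0.11, the chemokine gene Ccl3 by 0.64 ± 0.11, Slc11a1 by 0.62 ± 0.083, the macrophage elastase gene Mmp12 by 0.61 ± 0.084 and Clec4d by 0.60 ± 0.083, in the arrays in which the mean of the macrophage markers was higher by 0.33. The noncoding Rpph1, the RNA of ribonuclease P, rose by 0.68 ± 0.13.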
